A study of Mus musculus with 6 samples.

How the data were processed

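Hippocampal total RNA from 6 mice aged 2 to 3 months was measured on Affymetrix mouse expression arrays. According to the labels, 3 animals lacked IκBα in the brain (a floxed and a null allele of the gene with Nestin-Cre) and 3 littermate controls had the same alleles without the recombinase. The labels call the arrays biological repeats, so the spread between arrays of a group includes the spread between animals.

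The deposited values were on the log2 scale and had been made with RMA, per the submitters' processing notes, which combines background correction, quantile normalization and a summary of the probes of each probe set. The version of RMA, its probe annotation and a genome build are not given in the sources used here, so no coordinates are printed. RMA values are relative levels. Differences between low values are compressed by the background, and quantile normalization gives all arrays nearly the same distribution, so a change shared by most genes would be hidden. The sorted values of any 2 arrays differed by at most 0.10 on the log2 scale. Array medians lay between 6.08 and 6.13, and no 2 arrays were identical. Array data have no read depth, and the number of arrays limits the precision.

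Of the 45101 probe sets on each array, 64 control probe sets were left out of the tests. By GEO's platform annotation, which can be old, 34945 probe sets had 1 gene symbol, 932 had several and 9160 had no symbol here. Of those with 1 symbol, 34741 matched a RefSeq gene by Entrez identifier, and no symbol had to be updated. Probe sets with several symbols were not named. Each gene was represented by the probe set with the highest mean over the 6 arrays, which gave 18193 genes, 9010 of them with more than 1 probe set. No filter on dim genes was applied.

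Genes were compared between IκBα-deficient and control arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, genotype as the only term). The p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Differences are IκBα-deficient minus control on the log2 scale, with the standard error of the moderated fit. The 26 gene lists covered NF-κB and inflammatory genes, glial states, synapses, activity and stress responses, and markers of other cell types and of neighbouring tissue. They were tested with camera (preset correlation between genes of 0.01), adjusted over the 26 lists, and members were also adjusted over the list alone. The standard error of a list's shift comes from a linear model of the list mean over the 6 arrays. Camera with an estimated correlation and the rotation test fry were alternatives. The camera test compares a list with all other genes, while fry asks only whether a list moves one way. All lists, the design and most alternatives were fixed before the data were examined.

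The rule for naming genes was also fixed then. It took the targeted gene and 1 further gene, which had no probe set named here and is not analysed here. It took up to 12 genes per direction that passed the threshold with separated groups, filled up to 10 per direction with the smallest p, given as not passing, and the 4 members of each list with the smallest p. List members without a probe set of their own named here are given as counts.

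Alternatives were each array left out, the repeat number as a term, quantile normalization again, median centring, dim genes left out (lowest 40% by mean), other choices of probe set, a mean-variance trend with robust settings, array weights, other thresholds, a test without moderation, and list members shared between lists left out. A covariate for the sex of the animals was planned and not run, because the Y-linked genes were alike on all 6 arrays. Added after seeing the data were a covariate for the choroid plexus list, 1 for the meninges list, a covariate for the difference between 3′ and 5′ control probe sets, a fit without the 2 arrays in doubt, and the NF-κB list without its targeted gene.

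The scripts were tested on simulated data made from the means and spreads of this comparison, in 20 datasets of 18193 genes with 200 changed genes each. Of the genes changed by 1 on the log2 scale, 97.1% were recovered, and of those changed by 0.50, 57.4%. False calls were 5.12% of calls, and 4.96% of unchanged genes had an unadjusted p under 0.05. With 5 changed genes per dataset, 78 of 100 were recovered. A list shifted by 0.20 was called in 20 of 20 datasets. The simulated genes varied independently, so this does not cover genes that vary together between animals. Figures were drawn with matplotlib 3.10.9.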

Results

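Gene expression was profiled in the hippocampus of 3 mice without brain IκBα and 3 littermate controls. IκBα, the product of Nfkbia, binds NF-κB transcription factors and keeps them in the cytoplasm, and its own gene is an NF-κB target. Nestin-Cre deletes the floxed allele in the neural lineage, which gives rise to neurons, astrocytes and oligodendrocytes. Controls already carried 1 null allele. The question was which hippocampal transcripts differ when brain IκBα is lost. Values are RMA log2 values, given as mean ± SD with n = 3 arrays per group. Correlations between arrays, taken across probe sets, which are not independent replicates, lay between 0.992 and 0.998. The median SD of a gene was 0.08 in controls and 0.10 in IκBα-deficient arrays.

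Nfkbia itself was lower on every IκBα-deficient array than on every control array. Its brightest probe set (1420088_at) gave 10.35 ± 0.04 in controls and 8.95 ± 0.25 in deficient animals (SD, n = 3). That is a difference of -1.40 ± 0.12 (SE) on the log2 scale, or 2.64-fold lower, with an adjusted p of 0.057 (limma, Benjamini-Hochberg), just short of the threshold. The 3 other probe sets of Nfkbia that were bright in controls differed more. Probe set 1438157_s_at was 3.42-fold lower, 1449731_s_at 3.56-fold lower and 1448306_at 3.35-fold lower. In deficient arrays 1448306_at was at 5.56, a low value where RMA compresses differences, so its fold may be understated. The dim probe set 1420089_at was at 6.26 ± 0.29 in controls and 5.91 ± 0.13 in deficient arrays. Tested one by one among the 34945 probe sets with 1 symbol, 4 of the 5 passed, with adjusted p from limma of 0.00125 to 0.0471. With all other non-control probe sets included, 1420088_at had an adjusted p of 0.0629 and missed the threshold. Whether any of these probes lie in the deleted part of the gene is not known from the labels, so the values check the labels only as far as the transcript is lost.

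**Figure D1:**
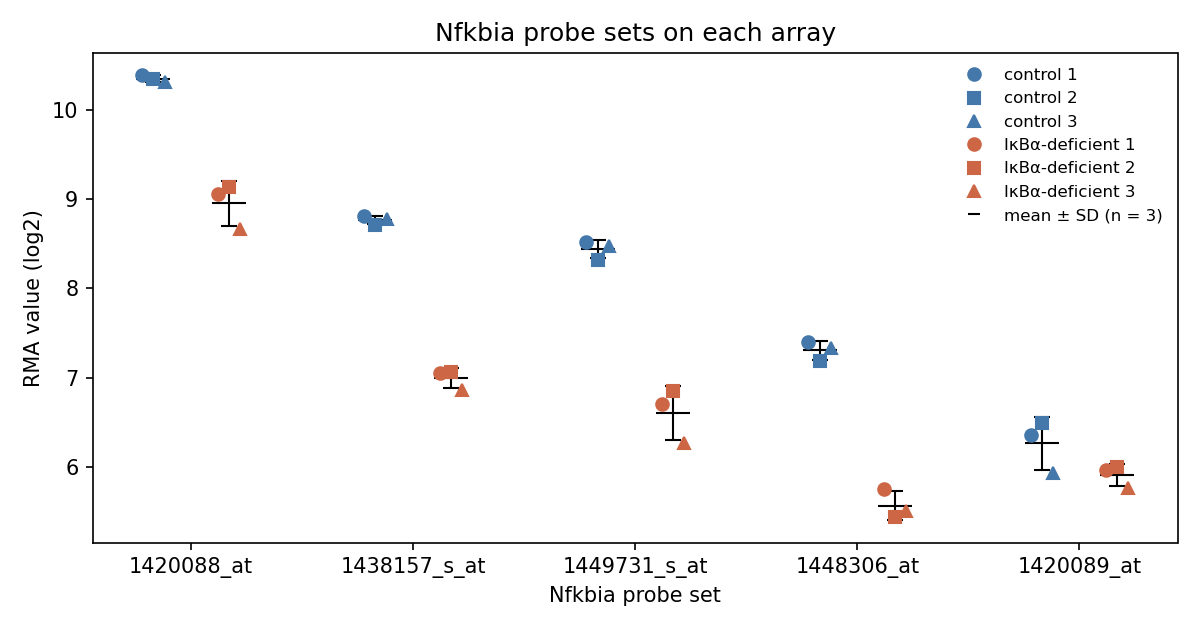
RMA log2 values (vertical axis) of the 5 Nfkbia probe sets (horizontal axis) on each array, with control arrays in blue and IκBα-deficient arrays in orange, and mean ± SD of n = 3 as black bars. In 4 of the probe sets the groups lie apart, as in 1420088_at with 10.35 against 8.95, while the dim 1420089_at shows 6.26 against 5.91.

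None of the other genes with the smallest p values passed the threshold. Among those higher in deficient animals were Nid2, a basement membrane protein, at 5.64 ± 0.17 against 4.97 ± 0.07, Aqp4, the astrocyte water channel, at 11.86 ± 0.11 against 11.41 ± 0.04, and Gbp7, an interferon-inducible guanylate-binding protein, at 8.06 ± 0.18 against 7.47 ± 0.06. Mamdc2 differed by 0.73, Ager by 0.74, Sema3b by 0.76, Angpt1 by 0.54, Mmp14 by 0.47, Creb5 by 0.44 and Acot1 by 0.39 on the log2 scale. These 10 genes had adjusted p of 0.559 to 0.658 (limma). On the lower side stood C3ar1, the receptor for a complement fragment, at 5.52 ± 0.09 against 5.89 ± 0.02, Galc, a lysosomal enzyme of myelin lipid breakdown, at 8.47 ± 0.09 against 8.87 ± 0.11, and Klf4, a transcription factor, at 7.74 ± 0.15 against 8.16 ± 0.14. Differences were -0.36 for Sftpc, -0.34 for Tyrp1, -0.30 for Shroom1, -0.38 for Cybrd1, -0.33 for Inhba and -0.32 for Orly, which turned to 0.028 when probe sets coded as shared between transcripts were left out. These 9 genes had adjusted p of 0.658 to 0.963 (limma). Some genes had probe sets of the other sign, among them C3ar1 with 2 of 3, Orly with 3 of 4, Galc, Tyrp1, Mmp14 and Sema3b with 1 of 3 each, Creb5 with 1 of 4, and Inhba and Angpt1 with 1 of 2 each.

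Over all 18193 genes, 0 were higher and 0 lower at an adjusted p under 0.05 (limma, Benjamini-Hochberg), and a test without moderation called 0 as well. At an unadjusted p under 0.05 there were 605 higher and 252 lower genes, 857 in all, where 910 would be expected by chance. The 3 deficient arrays lay wholly above the controls for 1080 genes and wholly below for 695, together 9.76% of genes, where chance gives 10%. Without control array 1, 5 genes were called higher, all in the choroid plexus list or following its mean within groups (r over 0.9). Nfkbia was called lower without IκBα-deficient array 3, with 1 gene in that direction. With the choroid plexus covariate, the counts at an unadjusted p under 0.05 were 215 higher and 146 lower.

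Among 26 measured genes of the NF-κB pathway and its feedback, 19 were higher and 7 lower in deficient animals. Nfkbia and Relb passed when adjusted over the list alone, and 0 over all genes. Relb, a subunit of the noncanonical pathway, was at 7.50 ± 0.11 against 7.11 ± 0.04, 1.31-fold higher, while the adhesion molecule Vcam1 was higher by 0.34, with 1 of 3 probe sets of the other sign, and the adaptor Traf2 by 0.24. The list had a mean difference of 0.03 and did not pass (camera adjusted p = 0.0752, and adjusted p = 0.651 with an estimated correlation). Left without Nfkbia, a choice made after seeing the data, its mean was 0.09 with a camera adjusted p of 0.00593, in a range of 0.00593 to 0.651 over all alternatives. The full list, Nfkbia included, was called without control array 3 (camera adjusted p = 0.0424) and without IκBα-deficient array 1 (adjusted p = 0.0356). Without IκBα-deficient array 2 the mean difference of the full list was -0.001, a value that includes the fall of Nfkbia itself.

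Complement and cytokine genes did not pass as lists. Of 17 measured complement genes, 10 were higher and 7 lower (mean difference 0.06, camera adjusted p = 0.258, but 0.00821 and called higher with the mean of all probe sets). The mean difference was 0.03 without IκBα-deficient array 2, and 1, C3ar1, passed when adjusted over the list alone and 0 over all genes. Cd55, an inhibitor of complement activation, was higher by 0.22, the serine protease C1ra by 0.23 and C1s1 by 0.20. Of 33 measured cytokines and chemokines, 18 were higher and 15 lower (mean difference 0.04, camera adjusted p = 0.494), with 0 passing over the list alone or over all genes. The mean difference was 0.026 without IκBα-deficient array 2 and 0.063 without IκBα-deficient array 3. The largest was Cxcl5 at 5.77 ± 0.62 against 5.09 ± 0.32, while Cxcl14 differed by -0.20 and Il33, a cytokine stored in nuclei of glia, by 0.16. Some members were dim, such as Il6 at 3.68 and Cxcl2 at 3.49 in controls, beside array medians of 6.08 to 6.13. A change in such genes could be hidden.

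Genes of antigen presentation were higher as a list in the deficient hippocampus. All 16 measured members were higher, by 0.23 ± 0.04 (SE) on average or 1.17-fold, and the list mean lay above every control array on all 3 deficient arrays, at 7.88 ± 0.06 against 7.65 ± 0.03 (SD, n = 3). The invariant chain Cd74 was at 7.08 ± 0.19 against 6.61 ± 0.15, the class I heavy chain H2-K1 at 10.13 ± 0.15 against 9.77 ± 0.10, and the class II chain H2-Ab1 at 6.09 ± 0.24 against 5.68 ± 0.03. H2-D1 was higher by 0.27. These 3 first-named genes passed when adjusted over the list alone, and 0 passed over all genes. The list passed with a camera adjusted p of 2.2e-08, the adjusted p was 0.0799 with an estimated correlation, and fry gave 0.0291. H2-Ab1 turned to -0.016 when probe sets coded as shared between transcripts were left out, and 2 of 9 probe sets of H2-D1 had the other sign.

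Interferon response genes were higher as well. Of 25 measured members, 24 were higher and 1 lower, by 0.21 ± 0.08 (SE) on average or 1.16-fold, and the list mean was 6.89 ± 0.12 against 6.68 ± 0.05 (SD, n = 3). The 3 deficient arrays stood at 6.75, 6.98 and 6.93, all above the highest control at 6.73. Gbp3 was at 7.89 ± 0.18 against 7.49 ± 0.05 and the immunity-related GTPase Iigp1 at 6.98 ± 0.24 against 6.58 ± 0.05. Ifit3 was higher by 0.37 and Ifitm3, a restriction factor against viral entry, by 0.34. The camera adjusted p was 4.51e-10, but the adjusted p was 0.362 with an estimated correlation, and 0 members passed over the list alone or over all genes. Members of the Gbp, Irg, Ifit and H2 families have near-identical copies, so which member a probe set reads is uncertain. The choroid plexus and meninges lists were also higher in deficient animals. IκBα-deficient array 2, with the highest interferon, antigen presentation and meninges means, had the widest gap between 3′ and 5′ control probe sets, and control array 3 had the lowest means of these 3 lists.

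**Figure D2:**
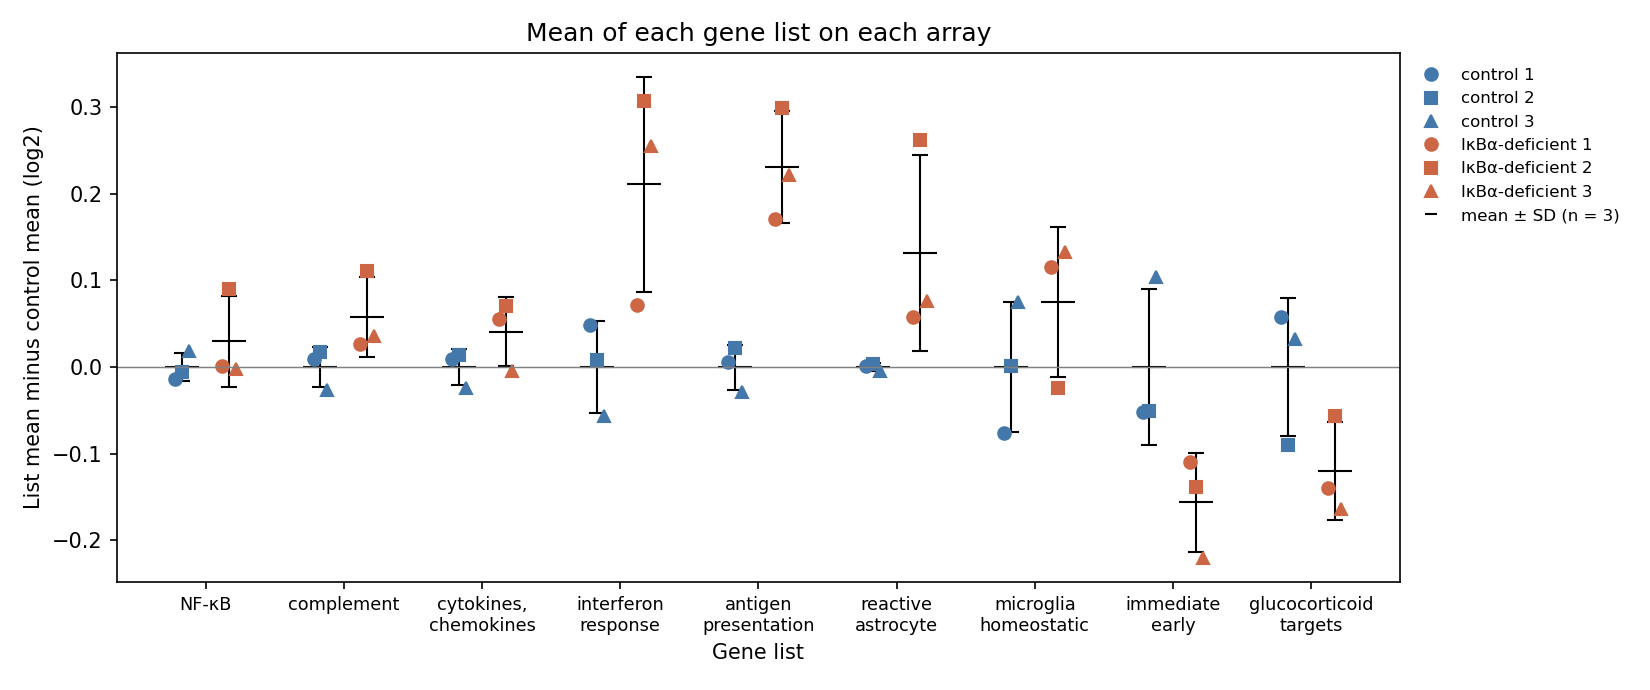
Mean of each of 9 gene lists on each array, as the log2 difference from the mean of the controls (vertical axis), with control arrays in blue, IκBα-deficient arrays in orange and mean ± SD of n = 3 as black bars. The interferon and antigen presentation lists lie above 0 by 0.21 and 0.23 in deficient animals, and the immediate early list lies at -0.16.

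Reactive astrocyte genes were higher by 0.13 ± 0.07 (SE) on average, with 24 of 35 measured members higher and 11 lower. Gfap, the astrocyte intermediate filament, was at 10.25 ± 0.06 against 9.95 ± 0.11, 1.23-fold higher, S1pr3 was higher by 0.23 and S100a10 by 0.21. Among the lower members were Hspb1 (-0.22), Lcn2 (-0.185, dim at 4.48 in controls), Serpina3n (-0.03) and Osmr (-0.02). The list shares members with other lists, such as Iigp1 (higher by 0.40) and Gbp2 with interferon and H2-D1 with antigen presentation. It is thus not separate from those lists, although its camera call was kept with shared members left out. Camera gave an adjusted p of 0.000416 for the list, the adjusted p was 0.362 with an estimated correlation, and 0 members passed over the list alone or over all genes. IκBα-deficient array 2 stood apart at 7.52 beside 7.32 and 7.33, and the shift was 0.07 without it (camera adjusted p = 0.0186). That array had the widest 3′ to 5′ gap, 2.02 on the log2 scale, and the highest meninges and pericyte means, 9.17 and 8.16. The call was lost with the meninges covariate (shift 0.03, adjusted p = 0.333). Homeostatic astrocyte genes were split, with 9 of 17 higher and 8 lower (mean difference 0.02, camera adjusted p = 0.936). Aqp4 passed when adjusted over this list alone, with 0 over all genes, while Sox9 differed by 0.18, S100b by -0.14 and the glutamate transporter Slc1a2 by -0.11.

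Homeostatic microglia genes were higher by 0.07 ± 0.07 (SE) on average, with 11 of 16 higher and 5 lower. The 5 lower members were Itgam (-0.20), P2ry12 (-0.15), Tmem119 (-0.08), Trem2 (-0.04) and Siglech (-0.03). Each of them was lowest among deficient arrays on IκBα-deficient array 2, which had the widest 3′ to 5′ gap. P2ry12 was at 7.53 there, beside 8.56 and 8.60 on the other deficient arrays and 8.26, 8.28 and 8.58 in controls. Itgam was at 4.30 there, beside 4.99 and 5.31 on the other deficient arrays. The list mean of IκBα-deficient array 2, 8.37, lay below control arrays 2 and 3, at 8.40 and 8.47. The purinergic-like receptor Gpr34 was at 7.28 ± 0.01 against 6.87 ± 0.18 and was the 1 member that passed when adjusted over the list alone, with 0 over all genes. P2ry13 was higher by 0.22 and the adaptor Tyrobp by 0.13. For the list, the camera adjusted p was 0.00266, and the adjusted p was 0.364 with an estimated correlation. The call was lost without control array 1 (adjusted p = 0.0862, shift 0.04) and without IκBα-deficient array 3 (adjusted p = 0.151, shift 0.05), and the shift was 0.12 without IκBα-deficient array 2. The choroid plexus and meninges lists were higher in the same animals, and the shift was 0.15 ± 0.10 (SE) with the former as a covariate and 0.19 ± 0.04 with the latter. Activated and lysosomal microglia genes did not pass (9 of 16 higher, mean difference 0.03, camera adjusted p = 0.413), although Lyz2, lysozyme, passed when adjusted over the list alone at 8.32 ± 0.10 against 7.94 ± 0.12, with 0 over all genes. The call was gained without IκBα-deficient array 2 (shift 0.09, adjusted p = 0.00313), while the shift was -0.002 without IκBα-deficient array 1 and -0.001 without IκBα-deficient array 3. Markers of infiltrating leukocytes did not pass, with 6 of 14 higher, a mean difference of 0.01, a median of -0.01 and a camera adjusted p of 0.936. Ptprc, the pan-leukocyte CD45 antigen, was higher by 0.23. None of the 14 passed over the list alone or over all genes.

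Immediate early genes, which neurons switch on within minutes of activity, fell as a list. Of 21 members 19 were lower and 2 higher, by -0.16 ± 0.06 (SE) on average, and all 3 deficient arrays lay below every control, at 9.36 ± 0.06 against 9.51 ± 0.09 (SD, n = 3). The fall was not shared by all members. Egr1 (0.005) and Egr3 (0.058) were the 2 higher ones, and Nr4a2 (-0.005), Dusp6 (-0.005) and Dusp1 (-0.011) were nearly level. Arc, a regulator of glutamate receptor traffic, was at 9.63 ± 0.13 against 10.13 ± 0.34, Fosb differed by -0.30, Jun by -0.22 and Fos by -0.16. As a list they had a camera adjusted p of 1.01e-05, the adjusted p was 0.362 with an estimated correlation, and 0 members passed over the list alone or over all genes. Control array 3 had the highest mean at 9.61, and the shift was -0.10 without it (camera adjusted p = 0.000654). The choroid plexus list was higher by 1.66 in the same animals, and with that list as a covariate the shift was -0.13 ± 0.10 (SE). Markers of CA1, CA3 and dentate gyrus neurons were lower by 0.10 on average in these animals, a shift that turned to 0.03 with the same covariate. Glucocorticoid targets were lower in 12 of 12 genes, by -0.12 ± 0.06 (SE) on average. Their list means overlapped between groups, with IκBα-deficient array 2 at 10.35 above control array 2 at 10.31. Sgk1, a glucocorticoid-induced kinase, was at 11.18 ± 0.14 against 11.55 ± 0.18, and Sult1a1 differed by -0.28. Camera gave an adjusted p of 0.000137 and the adjusted p was 0.362 with an estimated correlation, with 0 members passing over the list alone or over all genes.

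Neither synaptic list passed the test. Of 23 excitatory synapse genes 10 were higher and 13 lower (mean difference -0.01, camera adjusted p = 0.368). Camk2b was at -0.17 and Syn1 at -0.14, while Slc17a6, with the widest difference of the list, was at 0.34. The mean difference of this list was 0.008 without control array 2 and -0.026 without IκBα-deficient array 3. Of 17 genes of inhibitory synapses and interneurons 9 were higher and 8 lower (mean difference -0.02, median 0.004, camera adjusted p = 0.258, but 0.0259 and called lower with the mean of all probe sets). The neuropeptides Npy and Sst were at -0.18 and -0.17, while Slc32a1 was at 0.11, with 2 of 4 probe sets of the other sign. Markers of CA1, CA3 and dentate gyrus neurons were lower in 10 of 13 genes, by -0.10 ± 0.06 (SE) on average, with Tdo2 at -0.38, C1ql2 at -0.28 and Lct at -0.27. Their camera adjusted p was 0.00659, and the adjusted p was 0.489 with an estimated correlation. The call was lost without control array 2 (camera adjusted p = 0.104, shift -0.075), control array 3 (0.0507, shift -0.065) or IκBα-deficient array 2 (0.108, shift -0.083). Without control array 1 the shift was -0.155 (adjusted p = 1.45e-05), and with the choroid plexus covariate the shift turned to 0.03 (adjusted p = 0.597). The meninges covariate also ended the call (adjusted p = 0.711). Immature neuron genes were split, with 8 of 15 higher and 7 lower (mean difference 0.02, camera adjusted p = 0.861). That difference was -0.009 without control array 1 and 0.051 without IκBα-deficient array 3. Sox2 was higher by 0.33 and Dcx by 0.24, with 2 of 4 Dcx probe sets of the other sign. In these 4 lists, 0 members passed over the list alone or over all genes.

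Markers of the choroid plexus, the epithelium that secretes cerebrospinal fluid next to the hippocampus, showed the widest differences of any list. All 12 measured genes were higher in deficient animals, by 1.66 ± 0.73 (SE) on average or 3.16-fold, and 11 passed when adjusted over the list alone, with 0 over all genes. Clic6, a chloride channel protein, was at 9.10 ± 0.53 against 6.09 ± 2.23, Sostdc1 at 8.73 ± 0.46 against 7.17 ± 0.99, Calml4 was higher by 1.31 and the water channel Aqp1 by 1.27. The control arrays were unlike each other. Control array 1 had a list mean of 7.84 while control arrays 2 and 3 both had 5.80, and the deficient arrays had 8.66, 8.02 and 7.72. The list had a camera adjusted p of 2.46e-12, the adjusted p was 0.362 with an estimated correlation, and the shift was 2.34 without control array 1.

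**Figure D3:**
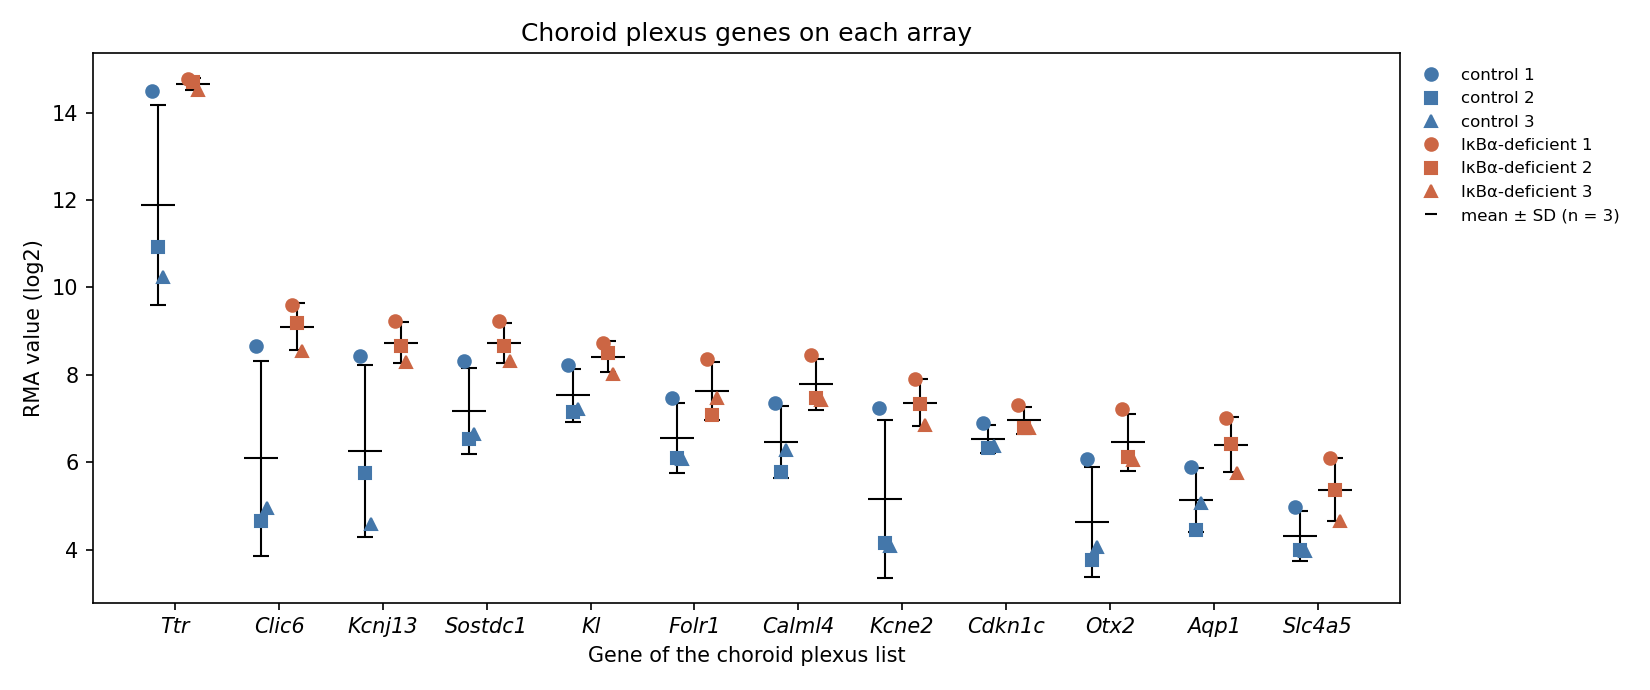
RMA log2 values (vertical axis) of the 12 choroid plexus genes (horizontal axis) on each array, with control arrays in blue, IκBα-deficient arrays in orange and mean ± SD of n = 3 as black bars. Control array 1 lies at the level of the deficient arrays, with a list mean of 7.84 against 5.80 on both other controls.

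Markers of the meninges and fibroblasts were higher in 12 of 12 genes, by 0.56 ± 0.31 (SE) on average or 1.47-fold. Igf2, insulin-like growth factor, was at 10.51 ± 0.52 against 9.30 ± 0.46, Igfbp2 at 9.51 ± 0.19 against 8.85 ± 0.25, the sulfate transporter Slc13a4 was higher by 0.98 and the proteoglycan Lum by 0.32. These 4 passed when adjusted over the list alone, with 0 over all genes. Of them, Igfbp2 and Lum were highest on control array 1 and IκBα-deficient array 1, as the choroid plexus list mean was. The fibroblast collagen gene Col1a1 differed by only 0.07. For the list, camera gave an adjusted p of 4.46e-08 and the adjusted p was 0.362 with an estimated correlation. IκBα-deficient array 2 had the highest mean, 9.17, and the shift was 0.31 without it (camera adjusted p = 9.63e-05). Pericyte and smooth muscle markers were higher in 10 of 11 genes, by 0.14 ± 0.16 (SE) on average, with 0 passing over the list alone or over all genes. Pdgfrb, the pericyte growth factor receptor, was higher by 0.39, and Abcc9 by 0.33, which turned to -0.125 without probe sets coded as shared between transcripts. In the camera test the adjusted p was 0.0189, the adjusted p was 0.657 with an estimated correlation, and the shift was 0.002 without IκBα-deficient array 2 (adjusted p = 0.623). The call was also lost without control array 3 (adjusted p = 0.325), and the shift turned to -0.14 with the meninges covariate (adjusted p = 0.162).

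The remaining lists did not pass, and 0 of their members passed over the list alone or over all genes. Oligodendrocyte and myelin genes were higher in 12 of 13 (mean difference 0.06, camera adjusted p = 0.187). That list was called higher without control array 3 (shift 0.11, adjusted p = 0.00855) and without IκBα-deficient array 2 (shift 0.12, adjusted p = 0.00235), while the shift was 0.004 without control array 2 and -0.02 without IκBα-deficient array 1. Oligodendrocyte precursor markers were higher in 5 of 8, with a mean difference of -0.003, a median of 0.04 and a camera adjusted p of 0.936. Endothelial markers were higher in 9 of 13 (mean difference 0.05, camera adjusted p = 0.198), with the VEGF receptor Kdr higher by 0.24. Their shift was 0.031 without control array 3 and 0.078 without control array 1. Thalamus and striatum markers were higher in 9 of 11 (mean difference 0.06, camera adjusted p = 0.413). Oxidative stress genes were higher in 6 of 11, with a mean difference of -0.005, a median of 0.04 and a camera adjusted p of 0.936. Red blood cell genes were higher in 3 of 5 (mean difference 0.05, camera adjusted p = 0.494) and sex-linked genes in 3 of 5 (mean difference 0.01, camera adjusted p = 0.936). The red blood cell shift was 0.006 without IκBα-deficient array 2 and 0.101 without IκBα-deficient array 3.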

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

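The list tests without single arrays and with an estimated correlation were set before the data were examined, but their use to weigh explanations, the choroid plexus and meninges covariates and the comparisons of list means between arrays were chosen after the results were seen. The test of genes at least 1.5-fold higher and both counts over splits were set before their results were seen.

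IκBα-deficient array 2 stood apart in data outside the gene comparison. Its 3′ control probe sets of Actb and Gapdh exceeded the 5′ ones by 2.02 on the log2 scale on average, while the control arrays had 0.646, 0.725 and 0.556 and the other deficient arrays 0.650 and 0.611. A wide gap of this kind is usual when RNA is partly degraded.

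The first pattern is the higher choroid plexus list in deficient animals. RNA degradation in IκBα-deficient array 2 is argued against as its whole cause, since the shift was 1.71 without that array (camera adjusted p = 6.53e-10), against 1.66 with it, a call that is lost over all arrays with an estimated correlation (adjusted p = 0.362). Choroid plexus tissue carried over at dissection is a candidate explanation, because control array 1 exceeded the other controls by 2.04 on the log2 scale, in 12 of 12 genes, with Clic6 at 8.66 there against 4.65 and 4.96, and Ttr, whose probe set is near the array ceiling, at 14.49 against 10.93 and 10.23. An effect of the deletion stays open beside it, as 2 of 3 deficient arrays lay above every control, control array 1 included. Of 43 genes outside the list that were at least 1.5-fold higher at an unadjusted p under 0.05, 34.9% followed the list mean within groups (r over 0.9) against 1.02% of 18138 other genes, so carryover may account for part of them and how many cannot be told. With the covariate their median difference went from 0.738 to 0.352, and 8 kept an unadjusted p under 0.05 (limma). All 10 named higher genes kept it, but they had been picked for the smallest p on these same arrays, so this decides nothing about carryover. Some of them are among the 43, such as Nid2, Gbp7 and Sema3b, the last with an r of 0.917 with the list mean. The list mean correlated with genotype at 0.749, which tends to widen the error of any gene, so the lost p values do not decide this.

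The second pattern is the higher antigen presentation and interferon lists, whose camera adjusted p with an estimated correlation were 0.0799 and 0.362. The estimate was -0.023 for antigen presentation, below the preset value, and 0.238 for interferon. Correlated members thus do not account for the lost call of antigen presentation, while they may for interferon. Fry kept antigen presentation (adjusted p = 0.0291) and not interferon (adjusted p = 0.299). A chance difference between animals stays open for interferon, and also for antigen presentation, where the tests were split. RNA degradation in IκBα-deficient array 2 is argued against as the whole cause, since without it the camera adjusted p was 7.25e-10 for antigen presentation (shift 0.20) and 7.09e-08 for interferon (shift 0.16). For the antigen presentation list mean, carried-over tissue as the whole cause is argued against by its shift with either covariate, each fitted alone. It was 0.24 ± 0.07 (SE) with the choroid plexus covariate (adjusted p = 1.72e-06), against 0.23 ± 0.04 before. With the meninges covariate it was 0.17 ± 0.03 (adjusted p = 2.3e-05). Members differed, so this does not cover each of them. H2-K1, B2m and H2-DMa were lowest among deficient arrays on array 2 (9.99, 11.55 and 7.86), as were H2-D1, H2-M3, Ctss and Ciita. B2m and H2-DMa lay below every control there. H2-Aa followed the meninges means, at 7.04, 7.18 and 6.81 in controls and 7.32, 8.21 and 7.28 in deficient arrays. H2-Eb1, Cd74 and Tap1 were also lowest on control array 3 and, like H2-Ab1, highest on IκBα-deficient array 2. Meningeal carryover stays open for these, and an effect of IκBα loss is a hypothesis. For interferon, carried-over tissue cannot be told apart from the genotype, as the shift of 0.21 ± 0.08 (SE) became 0.21 ± 0.14 with the choroid plexus covariate (adjusted p = 1.13e-06) and 0.12 ± 0.10 with the meninges covariate (adjusted p = 0.00392), both under 2 SE. The meninges list had means of 8.26, 8.31 and 7.77 in controls and 8.48, 9.17 and 8.36 in deficient arrays, lowest and highest on the same arrays as both lists.

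The third pattern is the fall of the immediate early list. High values on control array 3 do not account for all of it, since the list was called without that array (camera adjusted p = 0.000654), and RNA degradation in IκBα-deficient array 2 is argued against in the same way (adjusted p = 1.49e-05 without it), though the call over all arrays is lost with an estimated correlation (adjusted p = 0.362). Choroid plexus carryover cannot be told apart from the genotype, because the shift of -0.16 ± 0.06 (SE) became -0.13 ± 0.10 with the covariate, under 2 SE although camera gave an adjusted p of 0.00175. Handling and time of death, which move these genes quickly, are not recorded in the labels and may differ between the animals. The genotype stays open as well.

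With 3 arrays against 3 there are only 10 splits, too few for a share under 0.05. The real split gave 857 genes at an unadjusted p under 0.05 and the highest other split 1215, with 4 of the 10 splits giving at least 857. That highest split set control arrays 1 and 2 with IκBα-deficient array 2 against the rest. At an adjusted p under 0.05 (limma), the real split and the highest other both gave 0 genes, so all 10 gave as many.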

How the results depend on the processing

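The choroid plexus, meninges and 3′/5′ covariates, the fit without both arrays in doubt (control 1 and IκBα-deficient 2) and the NF-κB list without Nfkbia were chosen after seeing the data. Of 544 list values under alternatives, 490 kept their direction and side of the threshold or stayed uncalled, 36 lost the call, 16 gained one and 2 reversed. Of 1277 values of 72 named genes other than Nfkbia, 3 reversed and 1 passed the threshold. The cause was not tested unless stated.

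No gene was called higher except without control array 1, in a range of 0 to 5 over left-out arrays (Clic6, Ecrg4, Kcne2, Sulf1 and Ttr, of which Ecrg4, Kcne2, Sulf1 and Ttr were chosen after their values were seen). Clic6, Kcne2 and Ttr belong to the choroid plexus list, and Ecrg4 and Sulf1 followed its mean within groups (r of 0.997 and 0.99). Genes called lower were 0 to 1 over left-out arrays, 1 with median centring, dim genes left out (10916 genes tested), the mean of all probe sets, a mean-variance trend, array weights or an adjusted p under 0.1, and 4 as single probe sets, every one of them Nfkbia. Nfkbia differed by -1.40 with median centring, with dim genes left out and with the trend, by -1.42 with the mean of all probe sets and by -1.41 with array weights, and by -1.49 to -1.26 over left-out arrays. Its adjusted p (limma) ranged from 0.00379 to 1 over 19 settings, the highest with the choroid plexus covariate, where it differed by -1.52. The widest difference of any setting was -1.58, with the meninges covariate (adjusted p = 0.126). Genes lower at an unadjusted p under 0.05 were 173 to 455 over left-out arrays, 132 with dim genes left out, 470 as single probe sets, 440 with array weights, 146 with the choroid plexus covariate (higher 215), 586 with the meninges covariate, 462 with the 3′/5′ covariate and 420 without both arrays in doubt. The test without moderation called 0 genes, as did a threshold with a 1.5-fold change.

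Camera with an estimated correlation gave an adjusted p of 0.362 for the interferon, reactive astrocyte, immediate early, glucocorticoid, choroid plexus and meninges lists, 0.0799 for antigen presentation, 0.364 for homeostatic microglia, 0.657 for pericytes and 0.489 for the CA and dentate gyrus list. Fry gave 0.299 for the first 6 and for homeostatic microglia, 0.693 for pericytes and 0.51 for the CA and dentate gyrus list, and kept antigen presentation. Over left-out arrays the adjusted p was 6.54e-06 to 0.151 for homeostatic microglia, 0.00178 to 0.623 for pericytes, 1.45e-05 to 0.108 for the CA and dentate gyrus list and 0.0356 to 0.20 for NF-κB. The pericyte list was at 0.0779 with the mean of all probe sets, 0.081 without shared probe sets, 0.412 with array weights, 0.0856 with the choroid plexus covariate, 0.665 with the 3′/5′ covariate and 0.453 without both arrays in doubt, and reversed at 0.162 with the meninges covariate. The reactive astrocyte list was at 0.333 with the meninges covariate. The CA and dentate gyrus list was at 0.0818 with array weights, 0.103 with the 3′/5′ covariate and 0.711 with the meninges covariate, and reversed at 0.597 with the choroid plexus covariate. NF-κB was called without shared probe sets (0.00922) and without Nfkbia (0.00593), and with the mean of all probe sets complement (0.00821) and the inhibitory synapse list (0.0259). The oligodendrocyte list, at 0.00235 without IκBα-deficient array 2 and 0.00855 without control array 3, was also called with array weights (0.000882), the 3′/5′ covariate (0.00151), the meninges covariate (7.83e-05) and without both arrays in doubt (0.00352). Activated microglia were called without IκBα-deficient array 2 (0.00313), with the 3′/5′ covariate (0.00406), with the meninges covariate (0.00392) and without both arrays in doubt (0.0109). Without shared probe sets Orly turned to 0.028, H2-Ab1 to -0.016 and Abcc9 to -0.125. The red blood cell list had no value with dim genes left out, because too few members remained.

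The series describes 3 pairs of deficient animals and littermate controls, but does not say that the repeat numbers mark those pairs, so the numbers were not treated as pairs. Same-numbered arrays had correlations of deviations of 0.061, 0.238 and 0.195, and 5 of 6 arrays correlated best with their own number. For control array 1 this was 0.061 against 0.06 with IκBα-deficient array 2. Deviations from a group mean are tied to each other, so the matches are not independent and the count is only a weak hint. With the replicate block 0 genes were called, with 723 higher and 336 lower at an unadjusted p under 0.05, Nfkbia at -1.40 (limma adjusted p = 0.055), and no list call changed.

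Dim genes lie close to the array background, where RMA compresses differences, so low values such as those of 1420089_at limit what can be seen. The infiltrating leukocyte and red blood cell lists were also dim, with control means of 5.11 and 4.93.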

Other observations

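Some wide differences lay outside the fixed lists, in genes chosen here after their values were seen. Ecrg4 was higher by 2.21 in deficient animals, the coagulation factor F5 by 1.92, the extracellular sulfatase Sulf1 by 1.32, the collagen gene Col8a1 by 1.30 and the tight junction gene Cldn2 by 1.24, none past the threshold over all genes (limma). Of these, Ecrg4, F5, Sulf1 and Cldn2 were among the 15 genes that followed the choroid plexus list mean within groups (r over 0.9), and Col8a1 was just below at 0.872. Clic6, in the choroid plexus list, differed by more than any of these, at 3.01.

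The Y-linked genes Eif2s3y and Kdm5d were at 8.99 to 9.41 and 8.06 to 8.25 on all 6 arrays, while Xist was at 5.66 to 6.15. Of 10092 probe sets with no symbol or several symbols, 0 passed the threshold when tested by themselves (limma, smallest adjusted p = 0.505), and 211 had an unadjusted p under 0.05.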
